A study of Bos taurus and Bos grunniens and Bubalus bubalis with 15 samples.

How the data were processed

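Longissimus dorsi muscle was taken at slaughter from 9 Qinchuan cattle (3 intact males, 3 castrated males and 3 females), 3 yak and 3 buffalo, all aged 36 months, and frozen in liquid nitrogen. Total RNA was extracted with Trizol, biotin-labelled cRNA was made from 6 µg of it, and each sample was hybridised to 1 Affymetrix bovine array. The deposited table holds the intensity of 24128 probe sets on 15 arrays, as the authors summarised it, on a linear scale with no detection calls. The software, background step and normalisation are not given in the sources used here. The values do not share 1 distribution, so no quantile normalisation was made on the probe set values as deposited. An earlier step on single probes is not excluded. The array medians lay between 6.71 and 6.81 on the log2 scale with 16 added. Groups were taken from the sample labels, which call the arrays of a group biological replicates.

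The 112 control probe sets were set aside. The value 16 was added to each intensity before taking log2, without normalising again, and probe sets with a mean at or below the 40th percentile (6.42) were left out, so that 14409 of 24016 were tested and 9607 were not. The table of probe set annotation gave 1 gene symbol for 13318 probe sets and several for 86, and did not list 10724. Entrez identifiers matched 13283 of them to the current gene table, and 0 symbols changed. Of the probe sets tested, 9199 had 1 symbol, for 7139 genes, of which 1638 had several probe sets. Of the genes on the sex chromosomes looked for in every group, XIST and ZFY had probe sets, and DDX3Y, EIF1AY, KDM5D, UTY, USP9Y and EIF2S3Y had none.

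Linear models were fitted in R 4.3.3 with limma 3.58.1, using empirical Bayes moderation with a trend in mean intensity. The 3 contrasts among cattle groups and a test for any difference among them were fitted on the 9 cattle arrays. Yak minus cattle, buffalo minus cattle and buffalo minus yak were fitted on all 15 arrays, with cattle as the mean of its 3 group means. Adjusted p are Benjamini-Hochberg values over the probe sets of 1 contrast, two-sided, with a threshold of 0.05. With 3 arrays against 3 an exact permutation test of 1 probe set cannot go below 0.1. The steps were tested on simulated data of 14409 probe sets with the spread of these arrays. Values were drawn independently, with the same spread in every group and no outlying array. The shares below hold under those conditions only, and the intact males here spread more than the other cattle. The share of 2-fold changes recovered was 77.0% for castrated minus intact male, 78.8% for female minus intact male, 74.6% for female minus castrated male, 91.9% for yak minus cattle, 91.0% for buffalo minus cattle and 86.0% for buffalo minus yak. At 1.5-fold these shares were 27.5%, 26.0%, 29.9%, 59.1%, 59.4% and 39.1%, and 4.36% to 6.78% of the calls were wrong.

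The 34 gene lists were fixed before the data were examined, as were the contrasts, the filter, the rule for named genes and most of the alternatives. They cover matrix, collagen processing and basement membrane; adipocytes, fatty acid synthesis and oxidation, oxidative phosphorylation, citric acid cycle and glycolysis; slow and fast fibres, myogenic factors, growth, polyamines, protein breakdown, proteasome, ribosomal proteins and translation; sex-chromosome genes; antigen presentation, interferon, complement and macrophages; T, B and NK, endothelial, smooth muscle, blood and nerve cells; and hypoxia, clock, immediate early, chaperone, oxidative stress and cell cycle genes. Each gene was represented by its brightest probe set. A list's shift relative to other genes was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 102 tests of 34 lists and 3 contrasts in each family. Of the tests, 36 among cattle groups and 13 between species passed, and 0 and 0 did with a correlation estimated for each list. In fry, which asks whether a list's genes move on balance one way and does not compare them with others, 11 and 47 passed. Single genes are called over all probe sets tested and also adjusted over the list alone. Cell type markers are not exclusive: skeletal muscle itself expresses some, and CTSS, for example, stands in both the macrophage and the antigen presentation list.

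Genes named in the text are, per contrast, the 12 with the largest positive and 12 with the largest negative log2 fold change among those past the threshold, with 1 symbol and groups that do not overlap, and up to 4 called members of each list with the smallest p. Where fewer than 5 genes passed, the 10 with the smallest p were named. Genes known only by a locus number are mostly not written out. The overlap of the species contrasts was compared with the product of the shares called and with simulated data. In those data neither species differs from cattle, and only the shared cattle arrays link the contrasts. The overlap was also compared with fits that gave each species its own part of the cattle arrays.

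Alternatives were quantile normalisation, median centring, no filter or a filter at the 60th percentile, an added value of 1 or 64, other variance models, array weights, 1 probe set per gene, a minimum 2-fold change, other sets of arrays in the fit, the replicate number as a block, and leaving out each array in turn. The replicate numbers showed no pairing over all groups. After removing group means, arrays with the same number correlated across probe sets by a mean of -0.00713 over 30 pairs. Those with different numbers gave 0.00306 over 60, a value largely tied to the first as deviations sum to 0 within a group. Same-number correlations were positive between females and intact males (0.0652 to 0.137) or castrated males (0.00988 to 0.133). Between intact and castrated males they were -0.115 to 0.0790, so pairing within cattle is not excluded. No batch or date is given in the labels. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.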

Results

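Gene expression was measured in the longissimus dorsi, the long muscle of the back, of 15 animals aged 36 months. There were 5 groups of 3 animals. Intact males, castrated males and females came from Qinchuan cattle, a Chinese beef breed, and were born within 30 days of each other, of similar genetic background and reared alike. The other 2 groups were yak from Qinghai and water buffalo from Guangxi, whose sex is not given in the sources used here. Each animal's RNA was read on 1 bovine array with 24128 probe sets, and the values are hybridisation intensities, so there is no read depth and the number of arrays limits the precision. The array medians, on the log2 scale with 16 added, lay between 6.71 and 6.81, and the mean intensity per array between 304 and 364. Group values below are mean intensities ± SD with n = 3 arrays per group. Differences are log2 fold changes with their SE and limma's adjusted p, over 14409 probe sets bright enough to test. Said of genes, rose and fell mean higher or lower in the first group of a contrast, as no animal was measured over time.

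The 9 cattle arrays separated along a first principal component that held 54.7% of the variance, with the second at 10.7%. Intact males lay at one end, at -68.8, -26.9 and -7.29 for replicates 1, 2 and 3, castrated males between 3.76 and 13.1, and females between 23.7 and 25.8. Over all 15 arrays the first 2 components held 39.6% and 24.3%. Correlations across probe sets, which are not independent replicates, had a median of 0.974 over 15 pairs of arrays of the same group and 0.891 over 90 pairs of different groups. Intact male replicate 1 had the lowest mean correlation with its own group, 0.931. Intact male replicate 3 had a mean correlation of 0.945 with its own group, below the 0.956 with all other cattle arrays. On the first cattle component it also lay nearer castrated male 2 (3.76) than intact male 2 (-26.9). The ratio of 3' to 5' actin signal, a sign of RNA integrity, was 1.17 to 1.48 in intact males, 1.24 to 1.27 in castrated males and 1.22 to 1.33 in females. It was 1.49 to 1.93 in yak, above every cattle array, and 1.42 to 1.73 in buffalo, which overlapped the intact males. The same ratio for GAPDH was 1.13 to 1.34, 1.17 to 1.19 and 1.17 to 1.20 in the cattle groups, 1.20 to 1.26 in yak and 1.22 to 1.5 in buffalo. These control probe sets hold cattle sequence, so in the other species the ratios may also reflect how well transcripts bind.

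The submitters compared the cattle groups to find genes that differ between sexes, and castration is the first such contrast. Castrated males had far less collagen transcript than intact males. COL1A1, a chain of type I collagen, averaged 500.4 ± 54.8 in castrated and 3981 ± 1122 in intact males (log2 fold change -2.92, SE 0.22, adjusted p = 0.000581). Its partner chain COL1A2 fell by as much, with a log2 fold change of -2.76 (SE 0.18). COL3A1, the type III chain found beside it in soft tissue, fell from 10616 ± 1395 to 2766 ± 215 (log2 fold change -1.93, SE 0.17, adjusted p = 0.00185). FMOD, a proteoglycan that binds collagen fibrils, fell by a log2 fold change of -2.27 (SE 0.27). PI16, a marker of fibroblasts, had the smallest adjusted p of these genes, 3.27e-05, at a log2 fold change of -2.77 (SE 0.12). Of 24 measured members of the list of fibrillar collagens and matrix proteins, 12 fell, 0 rose and 12 did not pass, and 20 fell when adjusted over the list alone. The list's median log2 fold change was -1.33, with an adjusted p of 5.30e-17 in the set test that presets the correlation between genes, and adjusted p = 0.642 with an estimated correlation. Collagen metabolism is a theme the submitters drew from these same samples, so this count is not independent evidence of its direction. In the list of collagen processing and turnover 4 of 21 fell (11 adjusted over the list alone), among them PCOLCE, an enhancer of collagen propeptide cleavage, at -1.63 (SE 0.21) and the matrix metalloproteinase MMP2 at -1.26 (SE 0.22). The set's adjusted p was 0.000412, and adjusted p = 0.737 with an estimated correlation. Of 9 basement membrane genes 0 passed in limma, with 4 lower at an unadjusted p under 0.05 and 3 adjusted over the list alone. The shift of that list had a median of -0.52 (adjusted p = 0.00504 with the preset correlation, adjusted p = 0.737 with an estimated correlation). Leaving out 1 array changed the number of matrix genes that fell to between 5 (without castrated male 3) and 18 (without intact male 3), with 6 without castrated male 1, castrated male 2 or intact male 2. For collagen processing, 4 fell without intact male 1, 9 without intact male 3, 1 without castrated male 1 or castrated male 2, and 0 without castrated male 3 or intact male 2.

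**Figure D1:**
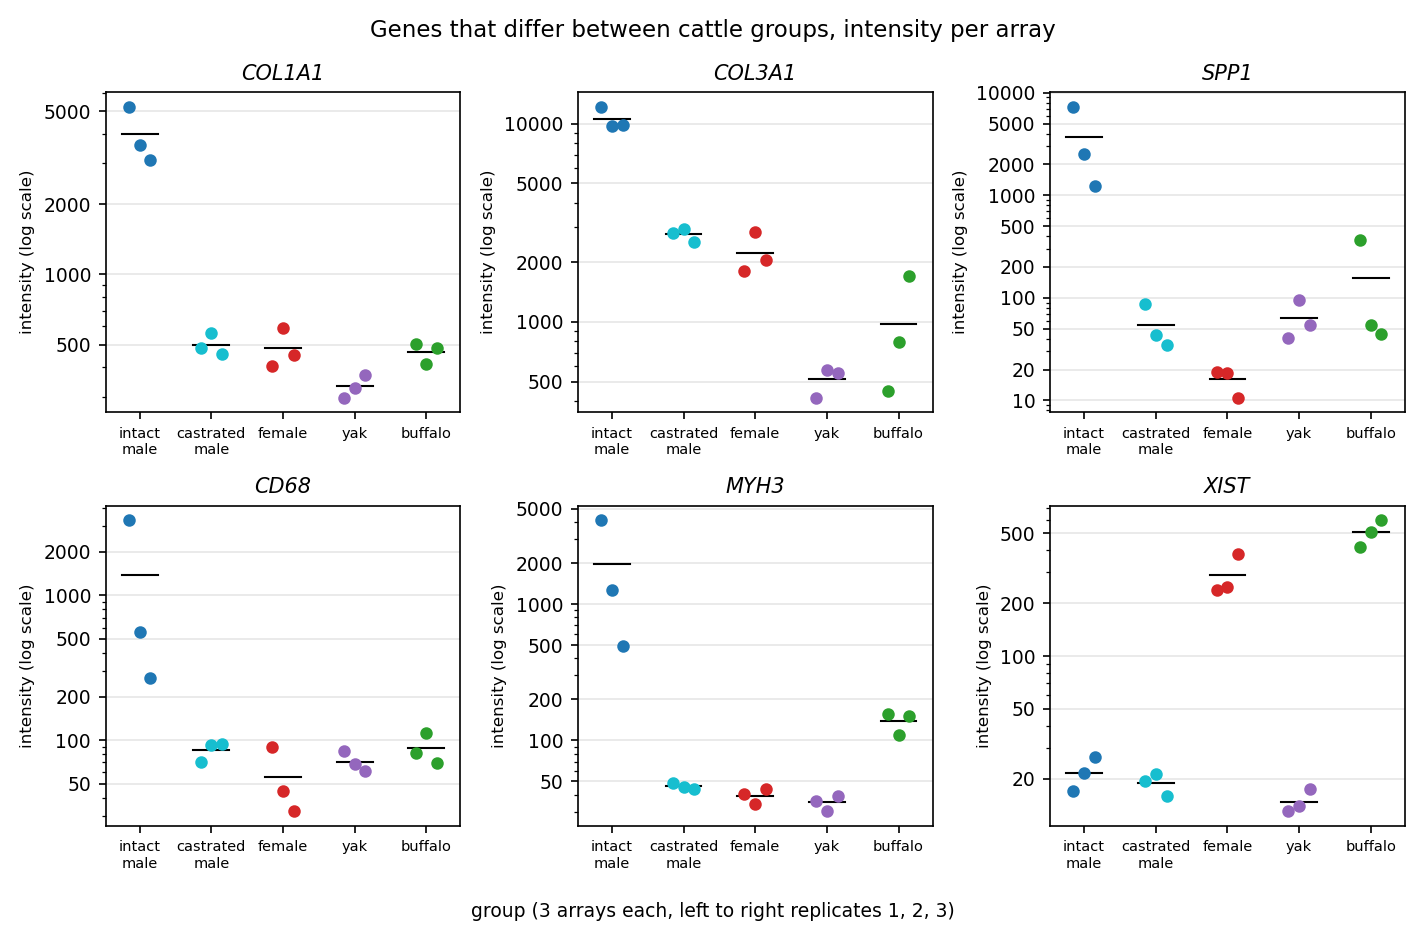
Intensity on each array (y axis, log scale, intensity units) of 6 genes in the 5 groups (x axis), with points for single arrays and short lines for the group mean, n = 3. COL1A1 averages 3981 ± 1122 in intact males against 500.4 ± 54.8 in castrated males and 482 ± 96.3 in females, and the 3 intact male arrays spread more for SPP1, CD68 and MYH3 than for COL1A1 and COL3A1.

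SPP1, GPNMB and MYH3 were also lower in castrated than in intact males. SPP1, or osteopontin, a secreted phosphoprotein of macrophages and injured tissue, fell from 3713 ± 3207 to 54.8 ± 27.6 (log2 fold change -5.41, SE 0.54, adjusted p = 0.00337). GPNMB, a glycoprotein of macrophages, had a log2 fold change of -3.83 (SE 0.54). MYH3, the embryonic myosin heavy chain, averaged 1966 ± 1914 in intact and 46.2 ± 2.34 in castrated males (log2 fold change -4.49, SE 0.58, adjusted p = 0.0106), the only 1 of 12 genes to pass in the list of myogenic factors (set adjusted p = 0.613). Of 17 measured macrophage markers 0 passed in limma over all probe sets, while 15 were lower at an unadjusted p under 0.05 and 15 fell adjusted over the list alone. Their median was -1.64 (adjusted p = 1.57e-06 with the preset correlation, adjusted p = 0.799 with an estimated correlation). The median was -0.82 without intact male 1, where 3 passed (10 adjusted over the list alone), and 5 passed without intact male 3 and 0 without any other array. On single arrays, list members were compared with their mean over the 6 castrated and female arrays. The macrophage median stood 3.62, 1.47 and 0.88 above it in intact males 1, 2 and 3, and the matrix median 1.85, 1.55 and 1.05. Of 15 endothelial and 11 smooth muscle and pericyte markers, 1 and 0 had an unadjusted p under 0.05 and 0 and 0 passed. Of nerve and Schwann cell markers, with a median of -0.26, 0 of 5 passed (2 lower adjusted over the list alone), as did 0 of 5 blood cell and 0 of 10 T, B and NK cell markers, with 2, 0 and 1 at an unadjusted p under 0.05. Interferon-response genes IFI6 and MX1 fell, with log2 fold changes of -2.88 (SE 0.53) and -2.69 (SE 0.53), the 2 of 14 members of that list that passed (7 adjusted over the list alone). The interferon set had a median of -0.63 (adjusted p = 0.000267, adjusted p = 0.666 with an estimated correlation).

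Other genes were higher in castrated than in intact males. NAMPT, which makes a precursor of NAD, rose from 846 ± 197 to 2285 ± 166 (log2 fold change 1.44, SE 0.23, adjusted p = 0.0223). ACACB, the acetyl-CoA carboxylase that controls fatty acid entry into mitochondria, rose with a log2 fold change of 2.29 (SE 0.43). CUL5, a ubiquitin ligase scaffold, rose by 1.17 (SE 0.12), and MITF, a transcription factor of lysosomal genes, by 1.16 (SE 0.15). Energy genes shifted upward by small amounts as sets, with few members passing, and 3 of the 4 sets lost the call without intact male 1. That array had the highest 3' to 5' ratios of the cattle arrays, 1.48 for actin and 1.34 for GAPDH. In the list of oxidative phosphorylation 1 of 45 rose, COX8B of cytochrome oxidase at 0.78 (SE 0.14), with a list median of 0.15 (adjusted p = 1.77e-05, adjusted p = 0.799 with an estimated correlation). Of 22 fatty acid oxidation genes 1 rose, the acyl-CoA dehydrogenase ACADM at 0.80 (SE 0.11), with a median of 0.17 (adjusted p = 0.0315, adjusted p = 0.799 with an estimated correlation). Of 15 citric acid cycle and 19 glycolysis genes 0 passed in limma, with 2 and 2 higher at an unadjusted p under 0.05. Their medians were 0.25 and 0.27 (adjusted p = 0.00363 and 0.0394, or adjusted p = 0.799 and 0.816 with an estimated correlation). Without intact male 1 the medians of oxidative phosphorylation, fatty acid oxidation, citric acid cycle and glycolysis were 0.07, 0.03, 0.10 and -0.03. Of these only oxidative phosphorylation then passed (adjusted p = 0.00880, against 0.391, 0.118 and 0.764). Fatty acid oxidation also lost its call without castrated male 1 (0.152), and glycolysis without castrated male 2 or 3 (0.0700 and 0.135). One chaperone of 25 rose, FKBP4, a partner of steroid receptors, at 0.98 (SE 0.20), and the chaperone set's median was 0.26 (adjusted p = 0.0229, adjusted p = 0.799 with an estimated correlation), a call lost without intact male 2 or 3 (0.0763 and 0.239). The remaining sets called were antigen presentation (-0.40), ribosomal proteins (-0.10) and the cell cycle (-0.26), with adjusted p of 0.0326, 0.00774 and 0.00989, or adjusted p = 0.764, 0.859 and 0.799 with an estimated correlation. All 3 lost the call without intact male 1 (adjusted p = 0.0762, 0.362 and 0.175, with medians of -0.42, -0.04 and -0.14), and antigen presentation also without castrated male 1 (0.103). In all, 211 probe sets differed between castrated and intact males, 90 higher and 121 lower (107 at least 2-fold), for 141 named genes, and 2952 had an unadjusted p under 0.05. Groups did not overlap in 3574 probe sets (24.8%), where chance gives 10%. After quantile normalisation 49.6% of the called probe sets were higher in castrated males, against 42.7% without it. The count was 995 without intact male 3, 51 without intact male 2, 41 to 57 without a castrated male (52, 57 and 41 for replicates 1 to 3) and 207 without intact male 1. Of 39 named genes that passed, 9 did so in every setting, COL1A1, COL1A2, COL3A1, FMOD, PI16, SPP1, CUL5, PHF3 and TRIM2. Of the 39, 32, 17 and 39 passed without intact male 1, 2 and 3, against 16, 17 and 11 without castrated male 1, 2 and 3.

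Females, too, had far less collagen transcript than intact males. COL1A1 averaged 482 ± 96.3 in females (log2 fold change -2.99, SE 0.22, adjusted p = 0.000319), COL1A2 817 ± 155 and COL3A1 2226 ± 536, with log2 fold changes of -3.18 (SE 0.18) and -2.26 (SE 0.17). SPP1 fell as well (log2 fold change -6.50, SE 0.54, adjusted p = 0.000670), and MYH3 fell to 39.3 ± 4.97 (log2 fold change -4.66, SE 0.58, adjusted p = 0.00760). In the matrix list 16 of 24 fell (21 adjusted over the list alone) and 0 rose, with a median of -1.56 (adjusted p = 1.49e-15, adjusted p = 0.642 with an estimated correlation), again on a theme that the submitters took from these samples. In collagen processing and turnover 9 of 21 fell (13, and 1 higher, adjusted over the list alone), among them CTSK, a collagen-cleaving cathepsin, at -2.83 (SE 0.47) and MMP2 at -1.60 (SE 0.22). That set had an adjusted p of 2.07e-05, and adjusted p = 0.716 with an estimated correlation. One basement membrane gene of 9 fell, NID2 at -1.18 (SE 0.23), and the set did not pass (0.0565), though it did without intact male 1 or female 2 (0.0318 and 0.0390). Matrix genes that fell numbered 7 to 20 when 1 array was left out, with 8, 7, 8 without female 2, female 3 or intact male 2. Collagen processing genes that fell numbered 0 without female 2 or female 3, 2 without intact male 2, 5 without female 1 and 12 without intact male 3.

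Macrophage and immune genes formed the next block. CD68, a lysosomal marker of macrophages, averaged 55.4 ± 30.1 in females and 1382 ± 1680.1 in intact males (log2 fold change -3.60, SE 0.73, adjusted p = 0.0318). The scavenger receptor MSR1 and the endotoxin co-receptor CD14 fell with log2 fold changes of -3.50 (SE 0.66) and -3.41 (SE 0.73). Of 17 macrophage markers 9 fell, 16 adjusted over the list alone, with a median of -2.39 (adjusted p = 9.52e-09, adjusted p = 0.737 with an estimated correlation). The number that fell was 13 without intact male 1 and 16 without intact male 3, but 3 without female 1 and 0 without female 2, female 3 or intact male 2. Antigen presentation genes fell in 5 of 17 (8 adjusted over the list alone), including the protease CTSS at -2.49 (SE 0.42) and the class II chain BOLA-DRA at -1.29 (SE 0.24), and the set passed (adjusted p = 0.000848, adjusted p = 0.666 with an estimated correlation). Complement and acute-phase genes fell in 4 of 14 (7, and 1 higher, adjusted over the list alone), among them C1S at -1.32 (SE 0.28) and PTX3 at -4.14 (SE 0.94), with a set adjusted p of 0.00326, and adjusted p = 0.666 with an estimated correlation. For antigen presentation, 0 fell without female 1, female 2 or intact male 2 and 1 without female 3. For complement, 2 fell without female 1, 1 without intact male 1, 7 without intact male 3 and 0 without female 2, female 3 or intact male 2. Immunity was also named by the submitters from these samples, so these lists are not independent evidence of direction. Interferon-response genes IFI6 (-3.06, SE 0.53) and IFITM1 (-0.98, SE 0.21) fell, 2 of 14 (3 adjusted over the list alone; adjusted p = 0.0132, adjusted p = 0.737 with an estimated correlation), a set call lost without female 1 or intact male 3 (0.0667 and 0.148). Endothelial, smooth muscle, blood and T, B and NK cell markers again gave 0 passing members, with 2, 1, 1 and 0 at an unadjusted p under 0.05, and medians of 0.16, -0.03, 0.11 and -0.07. Nerve and Schwann cell markers gave 0 of 5 too, with 2 lower adjusted over the list alone and a median of -0.21.

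Growth and protein turnover genes, further themes of the submitters and so not independent evidence, gave mixed results. The muscle ubiquitin ligases FBXO32, which marks atrophy, and FBXO40 rose in females, with log2 fold changes of 1.58 (SE 0.34) and 1.78 (SE 0.35), while the calpain CAPN2 fell at -0.74 (SE 0.16). That list of 19 had 3 higher and 1 lower, or 4 and 7 adjusted over the list alone, and 2 and 2 after quantile normalisation, and it did not pass as a set (adjusted p = 0.873). In growth, androgen and myostatin signalling 1 of 23 fell (1 higher and 3 lower adjusted over the list alone), IGFBP6, which binds IGF2, at -1.69 (SE 0.16), and 1 of 27 translation factors fell, EEF1A1 at -0.77 (SE 0.14). SAT1, which acetylates polyamines for breakdown, fell at -1.59 (SE 0.26), the 1 of 9 polyamine genes to pass (adjusted p of the set 0.508). Proteasome subunits gave 0 of 26, with 1 lower at an unadjusted p under 0.05. Among immediate early genes, MYC (-2.75, SE 0.53) and KLF4 (-1.92, SE 0.44) fell, 2 of 24 (3 adjusted over the list alone; adjusted p = 0.00321, adjusted p = 0.799 with an estimated correlation). The related nuclear receptor NR4A2 fell at -3.78 (SE 0.51). The metallothionein MT1A, which binds zinc and copper, averaged 1725 ± 376 in intact males, 389 ± 137 in castrated males and 124 ± 39.6 in females (log2 fold change -3.64, SE 0.28, adjusted p = 0.000403). One cell cycle gene of 18 fell, CCND3 at -0.85 (SE 0.18), against 8 adjusted over the list alone (adjusted p = 0.00168, adjusted p = 0.764 with an estimated correlation). MYLK2, a kinase of fast fibres, rose at 1.62 (SE 0.39), 1 of 13 fast fibre genes (adjusted p = 0.0447, adjusted p = 0.799 with an estimated correlation). Their median fell from 0.21 to 0.07 without intact male 1 (adjusted p = 0.175), and the set also lost its call without female 1, 2 or 3 (0.0736, 0.0665 and 0.0632). The clock gene CRY1 rose at 1.02 (SE 0.25), 1 of 9 (4 higher and 1 lower adjusted over the list alone; adjusted p of the set 0.141). Oxidative phosphorylation (0.12), the citric acid cycle (0.20), glycolysis (0.39) and ribosomal proteins (-0.11) had small median shifts, with adjusted p = 0.00363, 0.00740, 0.0315 and 0.0315, or adjusted p = 0.819, 0.799, 0.799 and 0.878 with an estimated correlation. Without intact male 1 these medians were 0.02, 0.11, 0.04 and -0.03 and none of the 4 passed (adjusted p = 0.220, 0.130, 0.620 and 0.550). Glycolysis also lost its call without female 3 (0.0806), and ribosomal proteins without female 2 or 3 (0.0815 and 0.0806).

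Of 8 measured sex-chromosome genes, 3 were higher in females. XIST, the RNA that silences one X chromosome, averaged 289 ± 82.6 in females against 21.7 ± 4.73 in intact and 18.9 ± 2.80 in castrated males (log2 fold change 2.99, SE 0.17, adjusted p = 8.68e-05). ZFX (1.27, SE 0.15) and KDM6A (1.08, SE 0.18), which escape silencing, rose with it. They were also the 3 that passed when adjusted over the list alone, and the set's adjusted p was 0.00363, with adjusted p = 0.642 with an estimated correlation. In all, 792 probe sets differed between females and intact males, 306 higher and 486 lower (75 and 290 at least 2-fold), for 478 named genes, and 3985 had an unadjusted p under 0.05. Groups did not overlap in 4764 (33.1%), where chance gives 10%. After quantile normalisation 46.4% of the called probe sets were higher in females, against 38.6% without it. Single arrays weighed heavily on the count, which was 2194 without intact male 3, 110 without intact male 2, 212, 77 and 87 without females 1, 2 and 3, and 534 without intact male 1. Of 62 named genes that passed, 12 did so in every setting, XIST, ZFX, SPP1, MYH3, GPNMB, NR4A2, MT1A, COL1A1, COL1A2, COL3A1, FMOD and IGFBP6. The number passing was 41, 16 and 61 without intact male 1, 2 and 3, and 27, 12 and 14 without female 1, 2 and 3.

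Females and castrated males differed in 3 probe sets. Of these, 2 detect XIST, higher in females by 2.86 (SE 0.12; adjusted p = 2.23e-05) and 3.10 (SE 0.17; adjusted p = 0.000127). The other detects the uncharacterised gene LOC515676, at 538 ± 147 in castrated males and 81.9 ± 26.2 in females (log2 fold change -2.50, SE 0.25, adjusted p = 0.0132). Leaving out castrated male 1 or castrated male 2, or fitting all 15 arrays, ended the call of LOC515676 (adjusted p = 0.00103 to 0.422 over the settings tried). The next genes by p did not pass: CEBPD, a transcription factor of the acute-phase response, at -2.26 (SE 0.34; adjusted p = 0.214), PITX1 at -0.87 (SE 0.14), ZFX at 0.96 (SE 0.15), AKR1C4 at -1.26 (SE 0.20), the small heat shock protein HSPB1 at -0.88 (SE 0.15; adjusted p = 0.278) and CYLD at -0.73 (SE 0.13). Without intact male 1, a setting chosen after seeing the data that alters only the pooled variance, 10 probe sets passed. The adjusted p of CEBPD was then 0.0253 (0.00781 to 0.854 over the settings tried) and that of HSPB1 0.0214 (0.0104 to 0.905). As sets, the sex-chromosome genes rose (1 of 8, 4 adjusted over the list alone; adjusted p = 7.52e-06, adjusted p = 0.396 with an estimated correlation). Chaperones were lower in females by a median of -0.31, with 0 of 25 passing in limma, 5 at an unadjusted p under 0.05 and 3 adjusted over the list alone (adjusted p = 5.63e-05, adjusted p = 0.716 with an estimated correlation). Macrophage (-0.72), immediate early (-0.58), antigen presentation (-0.25), complement (-0.28), collagen processing (-0.24), slow fibre (-0.14) and proteasome (-0.10) sets had negative medians with 0 members passing. Their adjusted p were 0.00116, 0.00321, 0.00347, 0.0394, 0.0461, 0.0447 and 0.0333, or adjusted p = 0.716 to 0.799 with an estimated correlation, and 3, 4, 1, 1, 2, 2 and 1 members had an unadjusted p under 0.05. Without intact male 1 the complement, slow fibre and proteasome sets lost the call (adjusted p = 0.0719, 0.0869 and 0.0778). Each of the 7 but the macrophage set lost it without at least 1 array of the groups compared. Over all probe sets 1088 had an unadjusted p under 0.05 and 2517 (17.5%) had groups that did not overlap, where chance gives 10%. A test for any difference among the 3 cattle groups called 283 probe sets (3453 at an unadjusted p under 0.05). It called 1174 without intact male 3, 44 without intact male 2, 101, 91 and 113 without castrated males 1 to 3 and 105, 61 and 75 without females 1 to 3.

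**Figure D2:**
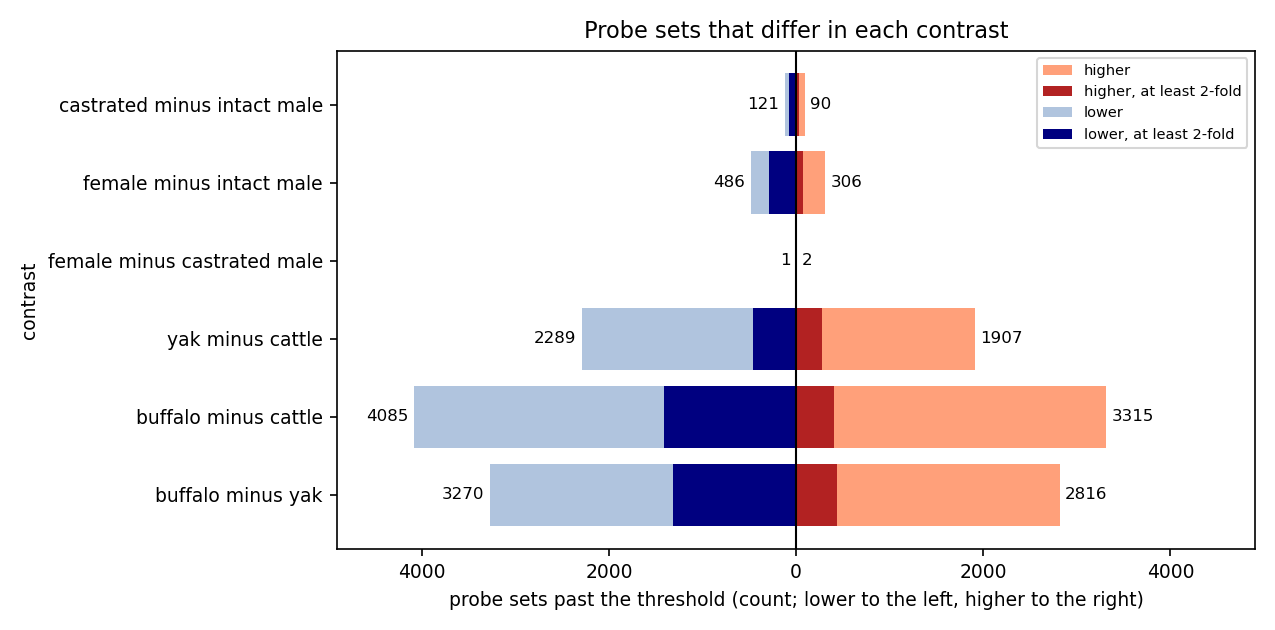
Probe sets higher (bars to the right of 0) and lower (bars to the left) in the first group of each contrast (y axis), as counts of the 14409 tested (x axis), with the part that differs at least 2-fold in the darker shade. The sex contrasts call 211, 792 and 3 and the species contrasts 4196, 7400 and 6086. Quantile normalisation makes the larger side the higher one for yak minus cattle, buffalo minus cattle and buffalo minus yak.

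Yak muscle was compared with cattle, as the mean of the 3 cattle groups, to profile differences between species. The array holds cattle sequence, so a difference can reflect the level of a transcript or how well it binds. Of the named genes, MYL3 and NMRK2 had the largest drops in yak. MYL3, the slow and cardiac essential light chain of myosin, averaged 369 ± 311 in yak against 6130.1 ± 2603, 7252 ± 2173 and 4297 ± 886 in intact males, castrated males and females (log2 fold change -4.20, SE 0.40, adjusted p = 1.47e-05). NMRK2, a muscle kinase of NAD synthesis, averaged 408 ± 34.9 against 5409 ± 1499.7, 6226 ± 2214 and 6036 ± 2009 (log2 fold change -3.75, SE 0.22, adjusted p = 2.45e-07). Of 12 slow fibre genes 9 fell (10 adjusted over the list alone) and 0 rose. They included the slow troponin TNNT1 at -0.53 (SE 0.09) and the slow myosin heavy chain MYH7 at -0.49 (SE 0.10), whose other probe set was at 0.13 (SE 0.17) and did not pass. The set's median was -0.51 (adjusted p = 0.00103, adjusted p = 0.779 with an estimated correlation), with 5, 7 and 7 falling without yak 1, 2 and 3. Fast fibre genes gave 0 of 13, with 1 at an unadjusted p under 0.05 (set adjusted p = 0.917). Matrix genes were lower in yak too. COL3A1 averaged 514 ± 86.6 in yak (log2 fold change -2.93, SE 0.28, adjusted p = 1.43e-05) and COL1A2 281 ± 55.7 (-2.69, SE 0.27). SPARC, which binds collagen in the matrix, averaged 515 ± 96.3 against 1589 ± 352 in castrated males and 1342 ± 285 in females (log2 fold change -2.15, SE 0.20, adjusted p = 1.04e-05). Of 24 matrix genes 17 fell, the same number adjusted over the list alone, with a median of -1.05 (adjusted p = 1.90e-06, adjusted p = 0.779 with an estimated correlation). Basement membrane genes fell in 7 of 9 (9 adjusted over the list alone), such as COL4A1 at -1.30 (SE 0.23) and LAMA4 at -1.03 (SE 0.15) (set adjusted p = 0.000551, adjusted p = 0.779 with an estimated correlation). Collagen processing genes fell in 7 of 21 (9 adjusted over the list alone; adjusted p = 0.0172, adjusted p = 0.824 with an estimated correlation). The matrix and collagen themes were named by the submitters for the sexes of cattle in this series, so these lists are not independent evidence. As intact males stood apart from other cattle in these genes, lists were also tested against each cattle group alone, which was chosen after seeing the data and is given in the order intact males, castrated males, females. Matrix medians in yak were then -1.97, -0.59 and -0.47, with 20, 10 and 8 of 24 lower (adjusted p = 2.12e-11, 0.00282 and 0.0166). Collagen processing medians were -0.86, -0.40 and -0.04 (adjusted p = 0.000227, 0.0674 and 0.593), so that set passed only against intact males. Basement membrane and slow fibre sets passed against each group (adjusted p = 0.000289, 0.00515 and 0.00114, and 0.00804, 0.000237 and 0.00420).

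Some genes of fat storage were lower in yak and some proteasome subunits higher. LPL, the lipase that loads fat cells, at -1.56 (SE 0.32), the fatty acid carrier FABP3 at -1.91 (SE 0.37) and SCD, the desaturase that makes oleate, at -1.69 (SE 0.28) fell. The adipocyte list had 7 of 20 lower and 1 higher (10 and 1 adjusted over the list alone; adjusted p = 0.0290, adjusted p = 0.779 with an estimated correlation), with 4 lower and no set call without yak 1 (0.107). Fatty acid synthesis had 5 of 12 lower (set adjusted p = 0.0781, but 0.0385 without female 1 and 0.0484 without yak 2). The fatty acid transporter SLC27A6 rose to 1662 ± 196 (log2 fold change 2.74, SE 0.53, adjusted p = 0.00203), and MAOA, which oxidises monoamines on the mitochondrial surface, to 1051 ± 220.4 (log2 fold change 2.76, SE 0.26, adjusted p = 1.20e-05). Proteasome subunits rose in 10 of 26, also adjusted over the list alone, with PSMC1 at 0.88 (SE 0.13) and PSMA7 at 0.67 (SE 0.10) (set median 0.29, adjusted p = 0.000353, adjusted p = 0.928 with an estimated correlation). The number was 4 without yak 1 or yak 2 and 15 without yak 3. Other genes of protein breakdown, ubiquitin ligases, calpains and cathepsins, had 3 of 19 higher and 4 lower, with a median of 0.07 (set adjusted p = 0.768). Macrophage markers fell in 5 of 17 (9 adjusted over the list alone; adjusted p = 0.00411, adjusted p = 0.976 with an estimated correlation), led by CTSS at -1.38 (SE 0.32), and 14, 8 and 14 fell without intact males 1, 2 and 3, against 3, 2 and 2 without yak 1, 2 and 3. These falls depended on the intact males: against intact males, castrated males and females alone the macrophage medians were -2.43, -0.64 and 0.05, with 17, 1 and 0 of 17 lower (adjusted p = 5.46e-07, 0.0509 and 0.977). Interferon genes fell in 7 of 14 (9, and 1 higher, adjusted over the list alone; adjusted p = 0.0172, adjusted p = 0.824 with an estimated correlation), such as MX1 at -1.99 (SE 0.39), with 3 falling without yak 1. They too passed as a set only against intact males, with 9, 0 and 2 of 14 lower (adjusted p = 0.000902, 0.283 and 0.0695). The proteasome set passed against each cattle group (adjusted p = 0.000902, 0.00401 and 8.08e-05), and the adipocyte set against all but castrated males (adjusted p = 0.0310, 0.0509 and 0.0490). Among the sets that did not pass, glycolysis had 7 of 19 lower and 1 higher, with GPI at -1.23 (SE 0.20) and LDHA at -0.66 (SE 0.14). That set passed without intact male 1, with 11 of 19 lower (adjusted p = 0.00137, against 0.116 with all arrays), and against females alone (0.0174). Oxygen supply and hypoxia response had 2 of 22 higher and 1 lower, 0 adjusted over the list alone (set adjusted p = 0.917). Myogenic factors had 1 of 12 higher and 4 lower, among them MYOD1 at -0.61 (SE 0.13). STAT5B, which carries growth hormone signals, rose at 2.11 (SE 0.31), EIF4EBP1, a brake on translation, at 1.77 (SE 0.30), and the clock receptor RORA at 1.66 (SE 0.24). FST, an inhibitor of myostatin, fell at -1.34 (SE 0.14).

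In all, 4196 probe sets (29.1%) differed between yak and cattle, 1907 higher and 2289 lower (281 and 461 at least 2-fold), and 52.8% of calls were higher after quantile normalisation against 45.4% without it. They named 2384 genes, 30 of them called both ways by different probe sets, and 5925 probe sets had an unadjusted p under 0.05. Yak did not overlap the 9 cattle arrays in 2776 (19.3%), where chance gives 0.909%. The count was 2281 without yak 1 and 2514 without yak 2. Of 127 named genes that passed, 68 did so in every setting, and 97, 108 and 114 passed without yak 1, 2 and 3. The actin 3' to 5' ratio was also higher in yak than on any cattle array, at 1.49 to 1.93 against 1.17 to 1.48. The GAPDH ratio was not, at 1.20 to 1.26 against 1.13 to 1.34.

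Buffalo differed from cattle in more genes than yak did, 4075 against 2384. The 3' to 5' ratios also reached higher, with some overlap. They were 1.42 to 1.73 for actin and 1.22 to 1.5 for GAPDH in buffalo, against 1.17 to 1.48 and 1.13 to 1.34 on the cattle arrays. LCAT, which esterifies plasma cholesterol, averaged 1738 ± 100.3 in buffalo against 142 ± 27.6, 111 ± 23.7 and 84.1 ± 9.12 in the cattle groups (log2 fold change 3.81, SE 0.13, adjusted p = 3.78e-10). FABP4, the fatty acid carrier of fat cells, averaged 810.1 ± 372 against at most 123 ± 82.2 (log2 fold change 2.77, SE 0.46, adjusted p = 0.000223). Without intact male 1, a setting for list members that was not planned beforehand, its adipocyte list more often went the other way. In that setting 3 of 20 were higher and 9 lower (median -0.28). TNNI3, the cardiac inhibitory troponin, rose at 2.65 (SE 0.21) and AGT, the precursor of angiotensin, at 2.36 (SE 0.15). SELENOP, which carries selenium in plasma, averaged 68.8 ± 4.52 in buffalo and 1894 ± 143 in females (log2 fold change -4.66, SE 0.16, adjusted p = 3.21e-10). The surface protein CD99 fell at -3.10 (SE 0.17) and the complement protease C1S at -3.09 (SE 0.23). XIST averaged 507 ± 87.3 in buffalo and 14.8 ± 2.27 in yak, beside 289 ± 82.6 in female and 21.7 ± 4.73 in intact male cattle. Its other tested probe set averaged 183 ± 44.2 in buffalo, below the 325 ± 38.9 of female cattle. Matrix genes were again lower, in 18 of 24 with 1 higher, the same numbers adjusted over the list alone, with SPARC at -2.57 (SE 0.20), DCN, a collagen-binding proteoglycan, at -1.23 (SE 0.09) and FMOD at -1.88 (SE 0.19). The median was -1.24 (adjusted p = 0.000470, adjusted p = 0.824 with an estimated correlation), on a list that is not independent evidence for the reason given for yak. Against intact males, castrated males and females alone the medians were -2.39, -0.94 and -0.79, with 21, 13 and 13 of 24 lower (adjusted p = 2.41e-08, 0.0462 and 0.0796), so the set did not pass against females. COL1A1 lay between 414 and 503 on the buffalo arrays, within the 405 to 590.1 of castrated males and females. Basement membrane genes fell in 8 of 9 (9 adjusted over the list alone), COL4A1 at -1.62 (SE 0.23) among them (adjusted p = 0.0171, adjusted p = 0.824 with an estimated correlation; 0.0553 without buffalo 2 and 0.0509 against castrated males alone). Macrophage markers fell in 8 of 17 (7 adjusted over the list alone), 13 without intact male 1, 14 without intact male 3 and 4 without buffalo 3, and the set did not pass (0.0566). It did without intact male 1, 2 or 3, castrated male 1 or female 3 (adjusted p = 0.00943, 0.0238, 0.00966, 0.0344 and 0.0316). The fall depended on the intact males, with medians of -2.50, -0.65 and 0.01 against intact males, castrated males and females alone, and 16, 4 and 3 of 17 lower (adjusted p = 0.000117, 0.215 and 0.977).

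More ribosomal protein and translation genes were lower than higher in buffalo, a balance that depended on normalisation and on the cattle compared. Of 58 ribosomal protein genes 29 fell and 3 rose (31 and 3 adjusted over the list alone), with RPS9 at -1.14 (SE 0.08), RPL18 at -0.99 (SE 0.07) and RPL23 at -0.81 (SE 0.05) lower and RPL37A at 0.45 (SE 0.04) higher. The set's median of -0.20 (adjusted p = 0.0300, adjusted p = 0.976 with an estimated correlation) shrank to -0.02 after quantile normalisation, with 19 lower and 10 higher. The set also lost its call without intact male 1, buffalo 2 or buffalo 3 (0.0716, 0.0682 and 0.153), and passed only against intact males of the 3 cattle groups (adjusted p = 0.00241, 0.113 and 0.0798). Of 27 translation factors 15 fell and 2 rose, EEF1G at -0.76 (SE 0.07) among them, but 7 fell and 8 rose after quantile normalisation (set adjusted p = 0.284). Growth genes fell in 10 of 23 with 1 higher, including TGFB2 at -2.73 (SE 0.17), FST at -1.95 (SE 0.14) and IGFBP7 at -1.95 (SE 0.11), and the set did not pass (0.0830). Fast fibre genes fell in 6 of 13 with 1 higher, such as ACTN3, the actinin of fast fibres, at -1.37 (SE 0.14). Glycolysis genes fell in 8 of 19 with 2 higher, such as PFKM at -1.36 (SE 0.20), while slow myosin MYH7 rose at 0.56 (SE 0.10). Without intact male 1, a setting for list members that was not planned beforehand, 5 of 12 slow fibre genes were higher and 3 lower (median 0.15). Oxidative stress genes fell in 14 of 31 and rose in 4, with the superoxide dismutase SOD1 at -1.69 (SE 0.14) and the metallothionein MT3 at 1.65 (SE 0.14). Oxidative phosphorylation had 11 of 45 lower and 7 higher, a balance that turned to 6 and 18 after quantile normalisation, and proteasome subunits had 7 lower and 7 higher, or 4 and 11. Among cells other than muscle, 4 of 15 endothelial and 5 of 11 smooth muscle markers fell, such as CLDN5 at -1.21 (SE 0.26) and RGS5 at -2.26 (SE 0.21). Of T, B and NK cell markers 3 of 10 rose, by at most 0.33 (NKG7, SE 0.10), and nerve markers rose in 3 of 5 and fell in 1. In all, 7400 probe sets (51.4%) differed, 3315 higher and 4085 lower (400 and 1410 at least 2-fold). Of the calls, 44.8% were higher, against 55.8% after quantile normalisation, while the median of all probe sets moved only from -0.03 to 0.06. Of the genes, 166 were called both ways, and 8283 probe sets had an unadjusted p under 0.05. Buffalo did not overlap the 9 cattle arrays in 4617 (32.0%), where chance gives 0.909%, and 123 of 149 named genes that passed did so in every setting.

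**Figure D3:**
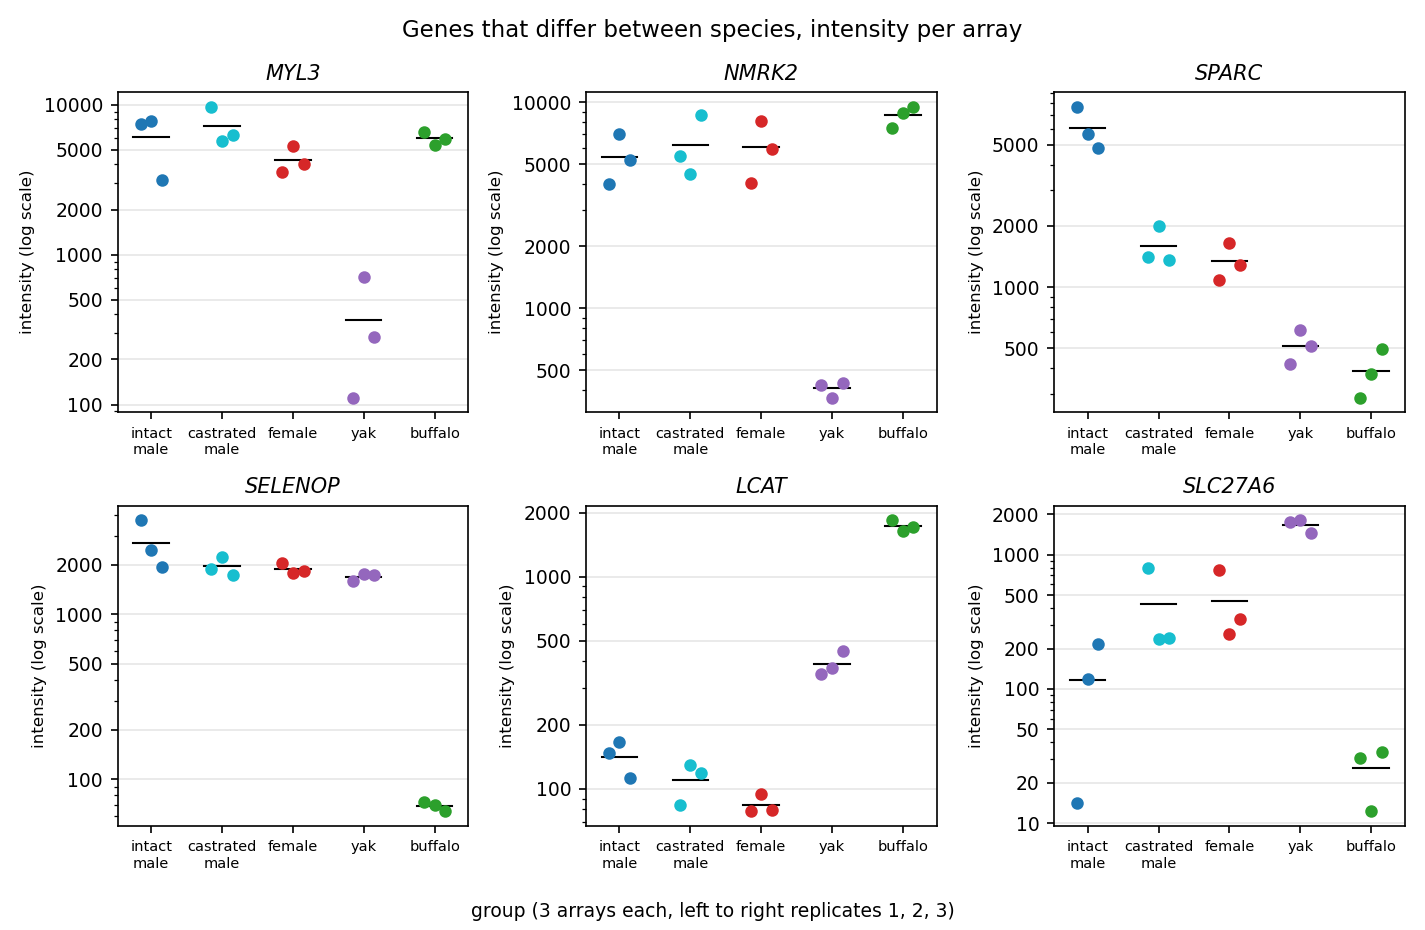
Intensity on each array (y axis, log scale, intensity units) of 6 genes in the 5 groups (x axis), with points for single arrays and short lines for the group mean, n = 3. MYL3 and NMRK2 are lower in yak than in every other group, SELENOP is lower and LCAT higher in buffalo, SLC27A6 is highest in yak and lowest in buffalo, and SPARC is lower in both than in cattle.

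Yak and buffalo shared part of their difference from cattle. Both were higher in 681 probe sets and lower in 1224, against 439 and 649 if the calls were independent, and they went opposite ways in 593. Some overlap comes from setting both species against the same cattle arrays. In simulated data neither species differed from cattle, and only the cattle arrays were shared. The fold changes then correlated across probe sets at 0.255, against 0.318 in the data, with a covariance of 0.00689 against 0.106. At most 1 probe set was called in both, which follows from simulating no difference. That simulation therefore does not give the overlap of species that each differ from cattle on their own. When each species was set against its own part of the cattle arrays, a median of 1321 probe sets went the same way and 392 opposite ways, with a correlation of 0.300 and a covariance of 0.104. The parts came from the same cattle groups. The split therefore does not separate a species difference from high matrix or macrophage values in intact males. Poorer binding of yak and buffalo transcripts to cattle probes would also give shared lower calls, and it was not tested for this overlap. Genes lower in both species included SPARC, COL4A1, FST and SOD1, with SOD1 at -0.81 (SE 0.14) in yak.

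Buffalo and yak were also compared with each other, and as the sex of neither is given, this contrast does not separate sex from species. On 1 tested XIST probe set the buffalo arrays lay at 420 to 595, above the 237 to 384 of female cattle. Yak arrays lay at 13.1 to 17.4 there, near male cattle. On the other tested XIST probe set buffalo lay at 143 to 230, below the 293 to 369 of female cattle, and yak at 23.1 to 27.2. Whether buffalo lay above or below female cattle thus depended on the probe set. The sexes of the groups may therefore differ, though low XIST in yak could also come from poor binding. MYL3 (4.31, SE 0.49) and NMRK2 (4.35, SE 0.27) were higher in buffalo, as were LPL (2.89, SE 0.39), FABP4 (3.53, SE 0.56) and cardiac actin ACTC1 (3.45, SE 0.57). SLC27A6 at 25.6 ± 11.7 in buffalo and 1662 ± 196 in yak (log2 fold change -5.37, SE 0.64, adjusted p = 2.69e-05), DISP1 (-4.71, SE 0.45), MAOA (-3.22, SE 0.32) and ACACB (-3.56, SE 0.36) were lower. Slow fibre genes were higher in 8 of 12 and lower in 1 (8 and 2 adjusted over the list alone), with MYH7 at 1.05 (SE 0.13) and MYOZ2 of the slow Z-disc at 1.00 (SE 0.15), and the set passed (median 0.51, adjusted p = 0.0186, adjusted p = 0.824 with an estimated correlation), though not without buffalo 2 (0.0553). Fast fibre genes were lower in 8 of 13, 4 without yak 3 or buffalo 3, and did not pass as a set (0.207). Ribosomal protein genes were lower in 26 of 58 and higher in 2 (26 and 3 adjusted over the list alone), with a median of -0.18 (adjusted p = 0.0250, adjusted p = 0.976 with an estimated correlation), and 16 and 7 after quantile normalisation. The call was lost without buffalo 2 or 3 (0.0577 and 0.152). Proteasome subunits were lower in 10 of 26 with 1 higher, PSMC1 at -2.04 (SE 0.16). Immediate early genes were lower in 11 of 24 (14 adjusted over the list alone), 6 without yak 1 or yak 2. Neither passed as a set (0.197 and 0.116), except the proteasome without yak 3 (0.0170). In all, 6086 probe sets (42.2%) differed, 2816 higher and 3270 lower in buffalo (442 and 1319 at least 2-fold), with 46.3% higher, against 53.9% after quantile normalisation. Groups did not overlap in 7956 (55.2%), where chance gives 10%, 7295 had an unadjusted p under 0.05, and 117 of 138 named genes that passed did so in every setting.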

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

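The tests of a single intact male array, of the share of muscle fibres and of how yak transcripts bind the probes were chosen after their results had been seen, and the others beforehand. For each count of probe sets, other splits of the same arrays were fitted. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05: the real split, 1 of 10, gave 211, 792, 3 and 6086 calls for castrated minus intact male, female minus intact male, female minus castrated male and buffalo minus yak, and the highest other split gave 0 in each. For yak minus cattle, with cattle pooled, the real split was the only 1 of 100 with as many calls (3002, highest other 1775). Buffalo minus cattle gave likewise 1 of 100 (6251, highest other 1192), and any difference among the cattle groups 1 of 100 (283, highest other 158). A share of 1 in 100 argues against a random grouping of the arrays for these 3 counts but does not exclude it. The other splits also keep some arrays of a real group together.

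Matrix and macrophage transcripts were higher in intact males than in females, with medians of -1.56 and -2.39 for females minus intact males. For the matrix genes the authors' normalisation is argued against as the whole cause, since 16 of the 16 called lower in females kept their call after quantile normalisation. That count does not cover the macrophage markers. A single array is argued against too: 19 of 24 matrix genes, and 15 of 17 macrophage markers, had intact males 2 and 3 both above all 6 castrated and female arrays. Chance gives 3.57% for 1 gene, but members of a list may move together, so they are not independent tests. The same held for 9 of 14 interferon and 11 of 58 ribosomal protein genes, and for 0 of 15 endothelial and 0 of 11 smooth muscle markers. A lower share of muscle fibres that raises all other cell types alike is argued against. Endothelial and smooth muscle medians (0.16 and -0.03) lay at least 1.53 from the matrix and macrophage medians. Matrix and macrophages alone taking the place of fibres would not raise vessel markers, so a lower share of that kind stays open. Against the mean of the 6 castrated and female arrays, fast fibre medians were -0.52, -0.03 and -0.03 on intact males 1, 2 and 3. Glycolysis medians were -0.88, -0.08 and 0.10, and slow fibre medians 0.04, 0.11 and -0.05. Nerve and Schwann markers, 5 in number, had a median of -0.21. Open and untested are the sex difference that the design names and, as a hypothesis, injured or regenerating muscle in the intact males, which may also go with MYH3 at 4129, 1277 and 492.0 on their 3 arrays against at most 48.8 in other cattle. Counting fibres with central nuclei or with MYH3 protein in sections of the same muscles would decide it.

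Buffalo had more probe sets at least 2-fold lower than at least 2-fold higher than cattle, 3.53 to 1, against 1.64 to 1 in yak. Quantile normalisation left 1.99 to 1, which argues against the authors' normalisation as the whole cause. Poorer binding of buffalo transcripts to cattle probes cannot be told apart from a lower level. Other probe sets of the same genes shared the direction in 76.6% of 529 cases for lower calls and 71.6% of 134 for higher calls, a difference, higher minus lower calls, of -4.92 points (Fisher exact p = 0.26, two-sided), and divergence along a whole gene would lower all of its probe sets. A difference between the species, which the design names, stays open as untested. As all buffalo came from Guangxi, the design cannot tell species apart from place of origin. Processing of the buffalo arrays was not tested as a cause either. The 3' control probe set for ThrX, a bacterial RNA, averaged 755 in buffalo and at most 391.5 in another group. RNA integrity was not tested as a cause, though the GAPDH 3' to 5' ratio reached 1.5 in buffalo and 1.34 in cattle. The actin ratio reached 1.73 in buffalo and 1.48 in cattle. Sex is not given for the buffalo. It is argued against as the whole cause, as far as it acts as in cattle, since lower calls outnumbered higher ones against each cattle group. Against intact male, castrated male and female cattle alone the lower and higher counts were 1613 and 520, 1384 and 370, and 1392 and 438.

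Slow fibre transcripts were lower in yak than in cattle, in 9 of 12 genes. A single yak array is argued against, since at least 5 members were called lower whichever was left out, with list medians of -0.41, -0.54 and -0.53 against -0.51 with all. Against intact males, castrated males and females alone, a comparison chosen after seeing the data, 7, 8 and 6 of 12 were lower (adjusted p of the set 0.00804, 0.000237 and 0.00420). These p come from the set test that presets the correlation, and with an estimated correlation 0 of the 102 main tests between species passed. Poorer binding of yak transcripts cannot be told apart from a lower level: of 7 other probe sets of these genes 5 were lower and 3 of those called, which is too few to decide and would also follow from divergence along the gene. The species difference itself stays open as untested, and as all yak came from Qinghai, it cannot be told apart from place of origin. Sex is not given for the yak. It is argued against as the whole cause, as far as it acts as in cattle, since the fall held against each cattle group. RNA integrity also stays open and untested, as the actin 3' to 5' ratio was 1.49 to 1.93 in yak and at most 1.48 in cattle. The GAPDH ratio, at 1.20 to 1.26 in yak, lay within the 1.13 to 1.34 of the cattle arrays.

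Several signals appeared outside the probe sets tested. An XIST probe set left out as dim averaged 585 ± 172 (SD, n = 3) in buffalo and 12.4 to 17.8 in the other groups. Among probe sets left out as dim, 16 were at least 4-fold higher in buffalo than in cattle when tested, such as ADH1C at 397 ± 244 against 5.14 to 7.70 in the cattle groups. In yak there were 8, such as ARMC2 at 529 ± 269 against 9.53 to 58.5. The control probe set for the 5' end of the elongation factor EF1A averaged 7375 ± 1822 in intact males and at most 3536 in another group. Control probe sets for the 3' end and the middle of cyclophilin averaged 2119 ± 945 and 1191 ± 653 in intact males, against at most 1142 and 570.1. The 3' control probe set for ThrX, a bacterial RNA that some protocols add before labelling, averaged 755 ± 26.0 in buffalo and at most 391.5 in another group.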

How the results depend on the processing

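Every alternative was planned before the data were examined except the female minus castrated male counts of probe sets and of gene lists without intact male 1, median centring of list shifts, list shifts against single cattle groups and list members without intact male 1. Where construction does not show it, the cause was not tested. Of 258 counts under the alternatives, 184 stayed within 1.5 times the reported count and 74 moved further. The balance of calls turned under quantile normalisation in the species contrasts: 2092 higher and 1870 lower in yak, 4402 and 3482 in buffalo, and 3321 and 2844 in buffalo minus yak, against 1907 and 2289, 3315 and 4085, and 2816 and 3270 as reported. Median centring turned it in yak (2222 and 1967) but not in buffalo (3118 and 4203) or buffalo minus yak (2317 and 3618), and no filter turned it in these 2 (7109 and 4820, 5275 and 3742) but not in yak (2469 and 2678). Of 4540 values of the single genes written out and of the lists, 4140 kept direction and side of the threshold, 352 lost the call, 46 gained it and 2 reversed, the macrophage shift in yak against females alone (adjusted p = 0.977, against 0.00411 with all cattle) and the glycolysis shift in castrated minus intact males without intact male 1 (adjusted p = 0.764, against 0.000993 to 0.816 over its alternatives). Of the genes the naming rule picked but the text does not give for that contrast, 3 in yak and 2 in buffalo changed sign against 1 cattle group alone, without passing there. They were C1QA (0.20, adjusted p = 0.794), C1QC (0.01, 0.984) and KDM6A (-0.07, 0.849) in yak against females, and in buffalo ZFX against females (-0.08, 0.771) and PER2 against castrated males (0.25, 0.364). Counts below run in the order castrated minus intact male, female minus intact male, female minus castrated male, yak minus cattle, buffalo minus cattle, buffalo minus yak and any cattle difference, with settings within 1.5 times left out. A minimum 2-fold change, stricter by construction, left 107, 365, 742, 1810, 1761 and 175 (all but the third), and 1 probe set per gene, which tests fewer, 115, 392, 2152, 3656, 3128 and 163. Array weights, whose estimation stopped short of its convergence tolerance, gave 3533, 5069, 14, 7021 and 5283 (the first 4 and the last), and all 15 arrays in the sex fits 718, 1911, 5 and 1206. Only the 2 groups compared, with fewer arrays for the variance, gave 37, 110 and 9 for the sexes. A filter at the 60th percentile left 1 for female minus castrated male, which had 10 without intact male 1, and no filter gave 11929 for buffalo minus cattle. Yak gave 2318 against castrated males alone and 2419 against females alone. Leaving out 1 array, which also leaves fewer arrays, gave 41 to 995 (castrated minus intact), 77 to 2194 (female minus intact), 2 to 10 (female minus castrated), 2281 to 4643 (yak), 6215 to 7877 (buffalo), 4720 to 5671 (buffalo minus yak) and 44 to 1174 (any). The replicate number as a block gave 143 for castrated minus intact and 642 for female minus intact. The numbers showed no pairing over all groups. Of 13, 14, 9, 8, 3 and 2 gene lists past the threshold, 0 passed in any contrast with an estimated correlation, and 3, 7, 1, 13, 19 and 15 did in fry, which tests a list against no change. Lists numbered 7 to 15, 10 to 15, 6 to 8, 7 to 9, 1 to 4 and 0 to 4 when 1 array was left out. Buffalo minus cattle had 5 lists with the mean over probe sets, 5 with no filter, 7 against intact males alone and 1 each against castrated males or females alone, yak minus cattle 4 against castrated males alone, and buffalo minus yak 1 after quantile normalisation and 6 with no filter. The overlap of 1905 stayed within 1.5 times under every alternative tried. Values near background limit the rest: with 16 added, differences among intensities below about 16 are compressed, and 9607 dim probe sets were not tested.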

Other observations

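Single genes of stress and signalling also differed between species, though their lists did not pass as sets. DNAJB1, a heat shock co-chaperone, was higher in yak at 2.24 (SE 0.52; 2614 ± 2474, SD, n = 3, against 304 ± 169.8 in females), while the chaperone list had 1 of 25 higher and 3 lower (adjusted p of the set 0.867). In buffalo the small heat shock protein HSPB6 was lower at -1.78 (SE 0.22) and the mitochondrial chaperone HSPA9 higher at 1.00 (SE 0.16), among 3 of 25 higher and 7 lower. Immediate early genes were lower in buffalo than in cattle in 6 of 24, such as IER2 at -2.76 (SE 0.42) and the survival gene MCL1 at -1.83 (SE 0.18), without the set passing (0.342). Clock genes rose in 3 of 9 in yak, among them the kinase CSNK1D at 0.76 (SE 0.11), which was also higher in buffalo at 0.47 (SE 0.11).

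Single regulators of energy and polyamine metabolism differed as well. PPARGC1A, a coactivator of mitochondrial genes, averaged 337 ± 47.8 in buffalo and 123 ± 30.0 in female cattle (log2 fold change 1.33, SE 0.20), and ARNT, the partner of hypoxia-inducible factors, was higher at 1.15 (SE 0.09), while myoglobin, MB, was lower at -0.58 (SE 0.06). The antizyme OAZ2, which marks ornithine decarboxylase for breakdown, was higher in yak at 0.82 (SE 0.19) and lower in buffalo at -1.61 (SE 0.19). KLF15, a transcription factor of amino acid breakdown, was higher in yak at 1.48 (SE 0.26), and the citric acid cycle enzyme IDH3A lower at -1.08 (SE 0.13). The Y-linked gene ZFY was left out as dim in all groups, with group means of 2.57 to 5.23.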
